A study of Sus scrofa with 9 samples.

How the data were processed

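RNA sequencing of total RNA, isolated with Trizol, measured the transcripts of cultured porcine immature Sertoli cells in 9 libraries, 3 in each of 3 groups. Control cells were taken before heat. HS0.5 cells were held at 43 °C for 0.5 h and taken at 0 h of recovery. HS0.5-R36 cells had the same heat and 36 h of recovery at 37 °C. The labels do not say whether the replicate numbers 1 to 3 stand for separate cultures or animals. Every p-value therefore measures only the spread between these samples, which may be technical.

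Per the submitters' processing notes, base calls were made with bcl2fastq and reads were aligned with HISAT2 2.0.5. The deposited table gives FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library) for 20681 genes in each library, with a gene length and coordinates for each gene. The gene length is the deposited length in base pairs, per the file headers. The genome build is not given in the sources used here. Of 12660 genes that share a symbol with the reference table for Sscrofa11.1, 12646 (99.9%) overlapped that table's gene, and positions are read on that build. The table has 8 further lines that hold no values, and these were not used here. A symbol came from the file for 13457 genes and from the reference table of gene names for 689, and 6535 genes had no symbol. Symbols shared by several genes were given to the gene of highest expression, and 242 other genes kept their ID alone.

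FPKM multiplied by gene length gave whole multiples of a constant in every library, for 100% of values within a tolerance of 1e-06, so reads per gene could be recovered. The recovered totals were 18110565 to 21034021 reads per library. The FPKM imply a library size of 0.902 to 0.973 times the recovered reads in the control and HS0.5 libraries and 1.17 to 1.19 times in the HS0.5-R36 libraries. The geometric mean of these factors is 1.01. Some scaling between libraries had thus been applied by the authors before deposit, and the sources used here do not describe it. The deposited FPKM were used as they stand in the main test, and scaling alternatives were run beside it. Intervals on read ratios are exact binomial intervals at 95% for counting error only, since no molecular identifiers are described.

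Genes were tested if FPKM reached 1 in at least 3 of the 9 libraries, which left 11479. With R 4.3.3 and limma 3.58.1, log2(FPKM + 1) was fitted with 1 mean per group over all 9 libraries, with empirical Bayes moderation along the intensity trend. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with 0.05 as the threshold. Log2 values are differences of log2(FPKM + 1), so the added 1 pulls changes of weakly expressed genes towards 0. The comparisons were HS0.5 with control, HS0.5-R36 with control and HS0.5-R36 with HS0.5. Replicate numbers were not used as pairs: correlations of libraries with the same number, after group means were removed, ran from -0.43 to 0.26, and 2 of 9 libraries matched best with a library of their own number.

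Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists. Of 34 lists written beforehand, 32 had at least 3 tested members. The camera test with an estimated correlation per list and fry were run as alternatives. The fry test asks whether a list's genes move, on balance, in 1 direction, and does not set them against other genes. The groups, comparisons, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined.

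Genes were named by a rule. The largest rises and falls among genes with a symbol that passed, whose groups did not overlap, and whose mean FPKM was at least 10 in the higher group, were named: 6 each way, or 4 each way for HS0.5-R36 with HS0.5. Up to 4 passing members of each list that passed, and up to 2 of each other list, were named, or the most expressed member where none passed. A preset group of heat shock, Sertoli and cell cycle genes was always named where measured. Of these, HSPA1A had no match under its own symbol and was taken by its alias HSP70.2, the name used here. HSPA1B, GATA4, FSHR and MKI67 had no match by symbol and were not analysed here. Any other gene named was chosen after its values were seen. A few genes that the rule or the marker lists name are not reported here.

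Alternatives covered other pseudocounts, filters, scalings, variance models, list tests, thresholds, a fit of only the compared groups, replicate numbers as blocks, and leaving out each library. Limma's library weights did not converge by restricted likelihood, so its gene-by-gene method was used. A voom fit on the recovered reads and removal of each library's trend with gene length (lowess, span 0.3) were added after the data were seen. So were marker lists of kidney tubules, of epithelia and of Sertoli lineage factors and hormones.

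The test was checked on simulated data, with 10892 genes tested. Expression rates came from the control libraries, and library sizes and 1 spread for all genes from all 9 libraries. Genes were drawn independently and no library stood apart, unlike in the real data. The test recovered 73.8% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold, all 175 in the right direction. Of 192 calls, 6.77% were false. In a simulated comparison in which no gene was changed, 0 of 10892 genes were called. Overlaps between comparisons that share libraries were set beside 100 simulated data sets without any group effect. These kept the covariance between genes, and 4 of them called genes in HS0.5 with control, 3195 at the most. False calls in the real data may thus be more than the check above gives. Strand use, trimming and the count tool are not given in the sources used here. GC content was not analysed here.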

Results

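The transcriptome of porcine immature Sertoli cells, the somatic cells that line the seminiferous cords of the testis and nurse germ cells, was measured before heat, at the end of a heat exposure and after recovery. The cells came from testes at 80 to 90 days of gestation and were kept in minimum essential medium with 10% serum, at 37 °C and 5% CO2, for 6 h before the exposure of 0.5 h at 43 °C. There were 3 control libraries from before heat, 3 HS0.5 libraries from 0 h after it and 3 HS0.5-R36 libraries from 36 h after it. The libraries held between 18110565 and 21034021 recovered reads, at which a single read in a gene of 1 kb corresponds to an FPKM of 0.0413 to 0.0576. On average 16264 genes had a value above 0 in control, 16247 in HS0.5 and 17338 in HS0.5-R36. Mitochondrial genes held 4.06% ± 0.09 of the reads in control, 5.31% ± 0.73 in HS0.5 and 5.30% ± 1.22 in HS0.5-R36 (SD, n = 3 each).

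The recovered libraries stood apart from the others on the first principal component, with 71.9% of the variance. The second component, with 17.1%, held control replicate 2 at 41.2 and the other control replicates at 6.1 and 1.5. Log2 expression correlated at 0.994 between control replicates 1 and 3, against 0.974 and 0.971 for the pairs with replicate 2. Short genes were higher and long genes lower in control replicate 2 than in the other controls, with medians of 0.39 and -0.28 log2 in the 1148 shortest and the 1148 longest genes. The short genes of the respiratory chain and the ribosome move with this library in the comparison at 0 h.

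**Figure D1:**
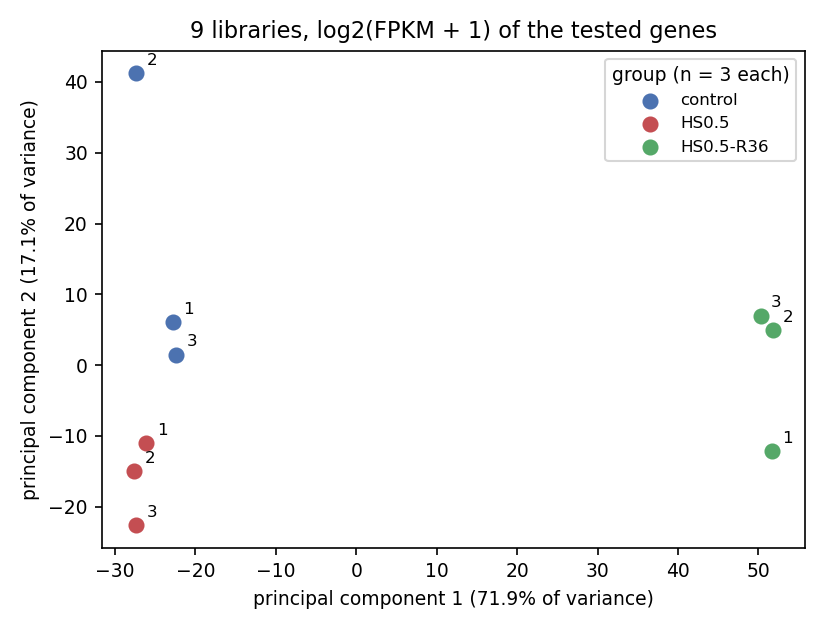
The 9 libraries by their first and second principal components of log2(FPKM + 1), coloured by group and numbered by replicate. The 3 HS0.5-R36 libraries lie apart on component 1 (71.9% of the variance), and control replicate 2 lies apart on component 2 (17.1%).

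The comparison of HS0.5 with control asks what changes by the end of the exposure. Control cells were taken before heat, so 0.5 h of further culture and the handling go with this contrast. The inducible chaperones of the HSP70 and HSP40 families, which heat shock factor 1 switches on when proteins unfold, rose furthest. Genes of cholesterol synthesis under control of the sterol sensor (INSIG1, SC5D, STARD4) and the splicing kinases CLK1 and CLK4, which act on the splicing factors that heat switches off, rose as well. The stress and growth arrest genes ATF3, GADD45G, JUN and CHAC1 fell. So did 13 of 180 small nucleolar RNAs, among them SNORA62, SNORD21 and SNORA73, while 4 rose. With each library's trend with gene length removed, 8 of the small nucleolar RNAs fell and 7 rose.

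HSPA6 (ENSSSCG00000047932, chromosome 4, 88970591 to 88985586) went from a mean FPKM of 0.0273 to 45.5 ± 26.5 (SD, n = 3), a log2 change of 5.35 ± 0.32 (SE, limma adjusted p = 6.5e-05). Its recovered reads went from 5 in the 3 controls to 8232, a ratio of 1700 (95% interval 727 to 5230, counting error only). HSP70.2 (ENSSSCG00000029160, chromosome 7, 23914603 to 23928196) went from 12.9 ± 2.15 to 250.0 ± 69.0, with a log2 change of 4.15 ± 0.20 (limma adjusted p = 5.8e-05). It belongs to a family of near-identical copies, so reads of its neighbours may be counted with it. DNAJB1, the HSP40 partner of HSP70, rose from 27.6 to 182 FPKM, a log2 change of 2.66, and the HSP110 gene HSPH1 from 43.1 to 98.2, a change of 1.14. HSP90AA1, the inducible HSP90, rose from 529 to 843 FPKM with a log2 change of 0.67 (limma adjusted p = 0.021). That call was lost without control replicate 1 (limma adjusted p = 0.072) and without HS0.5 replicates 1, 2 or 3 (0.053, 0.063 and 0.097). The constitutive HSPA8 (0.35, limma adjusted p = 0.12), the small heat shock protein gene HSPB1 (-0.17, 0.61) and the factor HSF1 itself (-0.13, 0.47) did not pass. Nor did the Sertoli genes SOX9 (0.30, 0.11), WT1 (0.27, 0.11) and AMH (-0.19, 0.36). HSPA8 did pass without control replicate 2 (0.48, 0.029), after quantile normalization (0.53, 0.025) and with library weights, which also called SOX9 and WT1 up (0.0048 and 0.02).

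**Figure D2:**
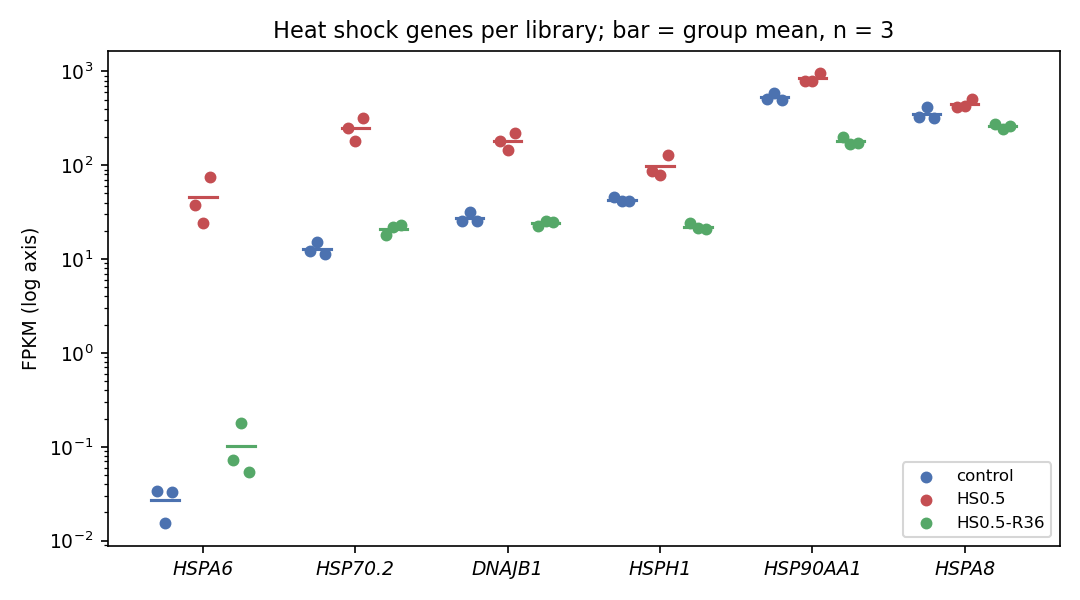
FPKM per library, on a log axis, of 6 heat shock genes in control, HS0.5 and HS0.5-R36 cells, with a bar at each group mean (n = 3). HSPA6 goes from 0.0273 FPKM in control to 45.5 in HS0.5, and HSPH1 and HSP90AA1 lie below their control values at 36 h.

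Other leading rises at 0 h were RSRP1, an arginine and serine rich splicing protein gene (1.94), the homeobox gene SIX4 (1.48) and INSIG1 (1.42 ± 0.08, limma adjusted p = 6.5e-05). SC5D, an enzyme of the sterol pathway, rose by 0.89, STARD4 by 0.76, CLK1 by 1.04 and CLK4 by 0.95. Leading falls were in SNORA62 (-2.10), SNORD54 (-2.09), the precursor of miR-221 (ssc-mir-221, -1.95), SNORD21 (-1.84), GADD45G (-1.73) and SNORA73 (-1.62). SNORD54 and ssc-mir-221 rest on few reads, 8 against 39 and 16 against 68 over the 3 libraries, with ratios of 0.212 (95% interval 0.0854 to 0.459) and 0.243 (0.131 to 0.423). ATF3, a transcription factor of the integrated stress response, fell by 1.28, CHAC1 by 1.05, GADD45A by 0.90, JUN by 0.89, TFEB by 0.76, NFKBIA by 0.67, SMAD7 by 0.65, FJX1 by 0.56, HERPUD1 by 0.53 and the arrest gene CDKN1A by 0.49. PARD6B, SKIL and IRF1 rose by 0.93, 0.86 and 0.40 and ADAMTS1 fell by 0.73. Leaving out a library ended some of these calls. Without control replicate 1, SNORD54, ssc-mir-221, HERPUD1, JUN, CDKN1A, PARD6B, ADAMTS1, STARD4, IRF1, SKIL and FJX1 were lost, with a limma adjusted p of 0.052 to 0.1. Without HS0.5 replicate 1, HERPUD1, CDKN1A, PARD6B, STARD4, IRF1, SKIL, FJX1 and NFKBIA were lost (0.052 to 0.1). Without HS0.5 replicate 2, SNORD54, HERPUD1, CDKN1A, ADAMTS1, STARD4, IRF1, SKIL, FJX1, NFKBIA and TFEB were lost (0.052 to 0.12), and without HS0.5 replicate 3 all of these but HERPUD1, with JUN, PARD6B, GADD45A and SC5D (0.052 to 0.18). SNORD54, CDKN1A, IRF1, SKIL and FJX1 were lost without HS0.5-R36 replicate 2 (0.055 to 0.081), these and STARD4 without HS0.5-R36 replicate 3 (0.054 to 0.069), SNORD54, IRF1 and FJX1 without control replicate 3 (0.055 to 0.062), and FJX1 without control replicate 2 (0.073).

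In all, 415 of 11479 genes changed at 0 h, 263 up and 152 down, and 44 of them at least 2-fold (24 up, 20 down). At an unadjusted p under 0.05 there were 3487. The count was 151 without control replicate 1, 165, 105 and 88 without HS0.5 replicates 1, 2 and 3, and 204 and 214 without HS0.5-R36 replicates 2 and 3. Rises made up 63.4% of the calls, and 51.8% of the 191 calls after each library was rescaled to the same sum (TPM). Of 32 gene lists, 6 passed camera (limma) at the preset correlation. The heat shock proteins and co-chaperones had 7 of 33 members up and none down, or 11 up and 1 down adjusted over the list alone, with a median of 0.13 (adjusted p = 0.00049, adjusted p = 0.83 with an estimated correlation). Cholesterol synthesis had 10 of 24 up, also 10 adjusted over the list alone (median 0.08, adjusted p = 0.00071, adjusted p = 0.37 with an estimated correlation). The G2/M and mitosis list, with no member called over all genes or over the list alone, had a median of 0.13 (adjusted p = 0.014). The junction and blood-testis barrier list (median 0.19, 0.0035) had 1 of 31 up by both counts, and the nuclear oxidative phosphorylation list (-0.29, 0.00013) and the ribosomal protein list (-0.23, 0.0017) had no member called by either. For these 4 lists adjusted p = 0.83 with an estimated correlation. Without control replicate 2 the junction (0.12), oxidative phosphorylation (0.21) and ribosomal (0.78, with a median of 0) lists no longer passed, while the heat shock (1.7e-06), cholesterol (8.2e-06) and G2/M (0.008) lists did. The junction and ribosomal lists did not pass with library weights (0.059 and 0.62) or after the length trend was removed (0.067 and 0.19). With an estimated correlation 0 lists passed, 1 did so unadjusted, and by fry 3 did: cholesterol synthesis (0.0023), p53 targets (0.0023) and the SR factors and CLK kinases (0.0084).

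Lists that did not pass at 0 h included the immediate-early genes, with 4 of 26 up and 6 down (6 and 12 adjusted over the list alone, camera adjusted p = 0.18 by limma). The p53 targets had 1 up and 3 down of 21 (2 and 6 adjusted over the list alone, 0.18), the SR factors and CLK kinases 3 up of 19 (0.087), and ER stress 2 down of 26 (4 adjusted over the list alone, 0.7). The NF-kB list had 1 down of 16 (1 up and 4 down alone), the TGF-beta list 1 up and 1 down of 19 (1 and 2 alone), and the interferon list 1 up of 15 (2 up and 1 down alone). The mitochondrially encoded genes had a median of 0.37 with none of 13 called (0.087), and the long genes watched for RNA quality a median of 0.46 with none of 7 called (0.087), 0.14 without control replicate 2. The mitochondrial list did pass in 6 settings, among them without HS0.5 replicate 1 (0.013) and after the length trend was removed (0.0048), the long genes without control replicate 1 or 3 (0.021 and 0.036), and the SR list after quantile normalization (0.034), without a filter (0.041) and after rescaling without mitochondrial genes (0.03). The p53 list passed without a filter (0.041). Median and mean differed in sign for the heat shock factors and the autophagy genes.

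The comparison of HS0.5-R36 with control asks what state the cells are in after recovery. No unheated library was kept as long as the recovered cells, so 36 h of further culture goes with this contrast. Most proliferation genes tested fell, among them licensing and replication factors (MCM5, ORC1, CDCA7, TK1) and mitotic regulators (AURKB, CCNB1, UBE2C, ANLN). So did immediate-early and matrix tension genes that serum and spreading cells switch on (FOSL1, CCN2, ANKRD1) and the cytokines IL11, CXCL8 and LIF. The protein folding genes HSPB1 and HSP90AA1 and most members of the TRiC chaperonin, which folds actin and tubulin, and of the proteasome lay below control. Most members of the cholesterol synthesis, autophagy and interferon-stimulated lists rose. These are counts of single genes: as groups none passed limma's camera with an estimated correlation, where the adjusted p was 0.068 for both proliferation lists and for cholesterol synthesis, 0.09 for the immediate-early and autophagy lists and 0.1 for the interferon list.

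CLDN8, a tight junction claudin (ENSSSCG00000012030, chromosome 13, 193562074 to 193564168), rose from 17 ± 2.29 to 135 ± 5.70 FPKM (SD, n = 3), a log2 change of 2.92 ± 0.10 (SE, limma adjusted p = 1.3e-07). The other leading rises were VAV3, a guanine exchange factor (1.88 to 20.3 FPKM, 2.89), the endocytic receptor LRP2 (2.75), CCDC187 (0.896 to 10.5 FPKM), the deiodinase DIO1 (2.49) and the fucosyltransferase FUT1. IL11 went from 247 to 9.71 FPKM (-4.54 ± 0.20, limma adjusted p = 3.6e-07), FOSL1 from 64.3 to 2.37 (-4.27), PHLDA1 from 65.7 to 2.81 (-4.13), CXCL8 from 72.6 to 3.85 (-3.93) and tissue factor F3 from 282 to 22 (-3.62). The miR-221 precursor ssc-mir-221 was listed at 0 in all 3 recovered libraries, with 0 reads against 68 in control, a ratio of 0 to 0.0438 (95% interval). CCN2 fell from 79.9 to 6.25 FPKM (-3.48) and TAGLN, of contractile cells, from 740.4 to 136.

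In all, 7248 genes changed at 36 h (63.1% of those tested), 3277 up and 3971 down, and 1711 of them at least 2-fold (702 up, 1009 down). Rises made up 45.2% of the calls. After rescaling to the same sum they made up 68.6% of 7167 calls, and 5068 of 7224 when mitochondrial genes and the 20 most abundant were left out of the sum. These rescalings moved the median of all genes by 0.32 and 0.35 log2 from -0.06, so whether more genes rose or fell depends on the scaling. With genes of at least 5 FPKM alone, 33.7% of 5286 calls were rises and the median moved by -0.145. The medians of the 14 lists that passed at 36 h kept their sign after these rescalings and after quantile normalization, while 10 others turned in each.

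Of the 32 lists, 14 passed camera (limma) at the preset correlation at 36 h. The G1/S and DNA replication list had 55 of 57 members down and none up (median -1.07, adjusted p = 3.1e-14, adjusted p = 0.068 with an estimated correlation), and 49 down after rescaling. The G2/M and mitosis list had 46 of 49 down, 47 adjusted over the list alone (-0.99, 1.6e-11, adjusted p = 0.068 with an estimated correlation). The immediate-early genes had 23 of 26 down and 2 up (-1.36, 1.4e-07, adjusted p = 0.09 with an estimated correlation). The proteasome had 29 of 31 down (-0.65, 1.5e-05, adjusted p = 0.59 with an estimated correlation) and the TRiC chaperonin and prefoldin list 10 of 10 (-1.07, 0.00034, adjusted p = 0.53 with an estimated correlation). Heat shock proteins and co-chaperones had 22 of 33 down and 4 up (-0.45, 0.0035, adjusted p = 0.63 with an estimated correlation), but 16 down and 8 up after rescaling and no pass after quantile normalization (0.13). Cholesterol synthesis had 18 of 24 up (0.72, 3.3e-05, adjusted p = 0.068 with an estimated correlation), autophagy 13 up and 3 down of 24 (0.45, 0.007, adjusted p = 0.09 with an estimated correlation) and the interferon list 9 up and 3 down of 15 (0.37, 0.0083, adjusted p = 0.1 with an estimated correlation). Counts adjusted over the list alone were the same unless given.

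Nuclear oxidative phosphorylation genes had 28 of 51 down, 27 adjusted over the list alone (-0.47, camera adjusted p = 0.0026 by limma, adjusted p = 0.86 with an estimated correlation), and a median of -0.02 after quantile normalization, where the direction of the test turned. Down as well were the NF-kB list (10 of 16 down and 1 up, -0.48, 0.007, adjusted p = 0.34 with an estimated correlation), YAP/TAZ targets (10 of 15 down and 1 up, -0.56, 0.0083, adjusted p = 0.34 with an estimated correlation), glycolysis (13 of 19 down and 2 up, 15 and 2 adjusted over the list alone, -0.56, 0.0098, adjusted p = 0.53 with an estimated correlation) and ER stress (16 of 26 down and 4 up, -0.57, 0.017, adjusted p = 0.34 with an estimated correlation). ER stress, glycolysis and YAP/TAZ did not pass after quantile normalization (0.3, 0.24 and 0.24), YAP/TAZ and the interferon list did not with genes of at least 5 FPKM alone (0.051 and 0.07), and oxidative phosphorylation did not with library weights (0.06). With an estimated correlation 0 lists passed and 6 did so unadjusted, and by fry 24 passed.

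**Figure D3:**
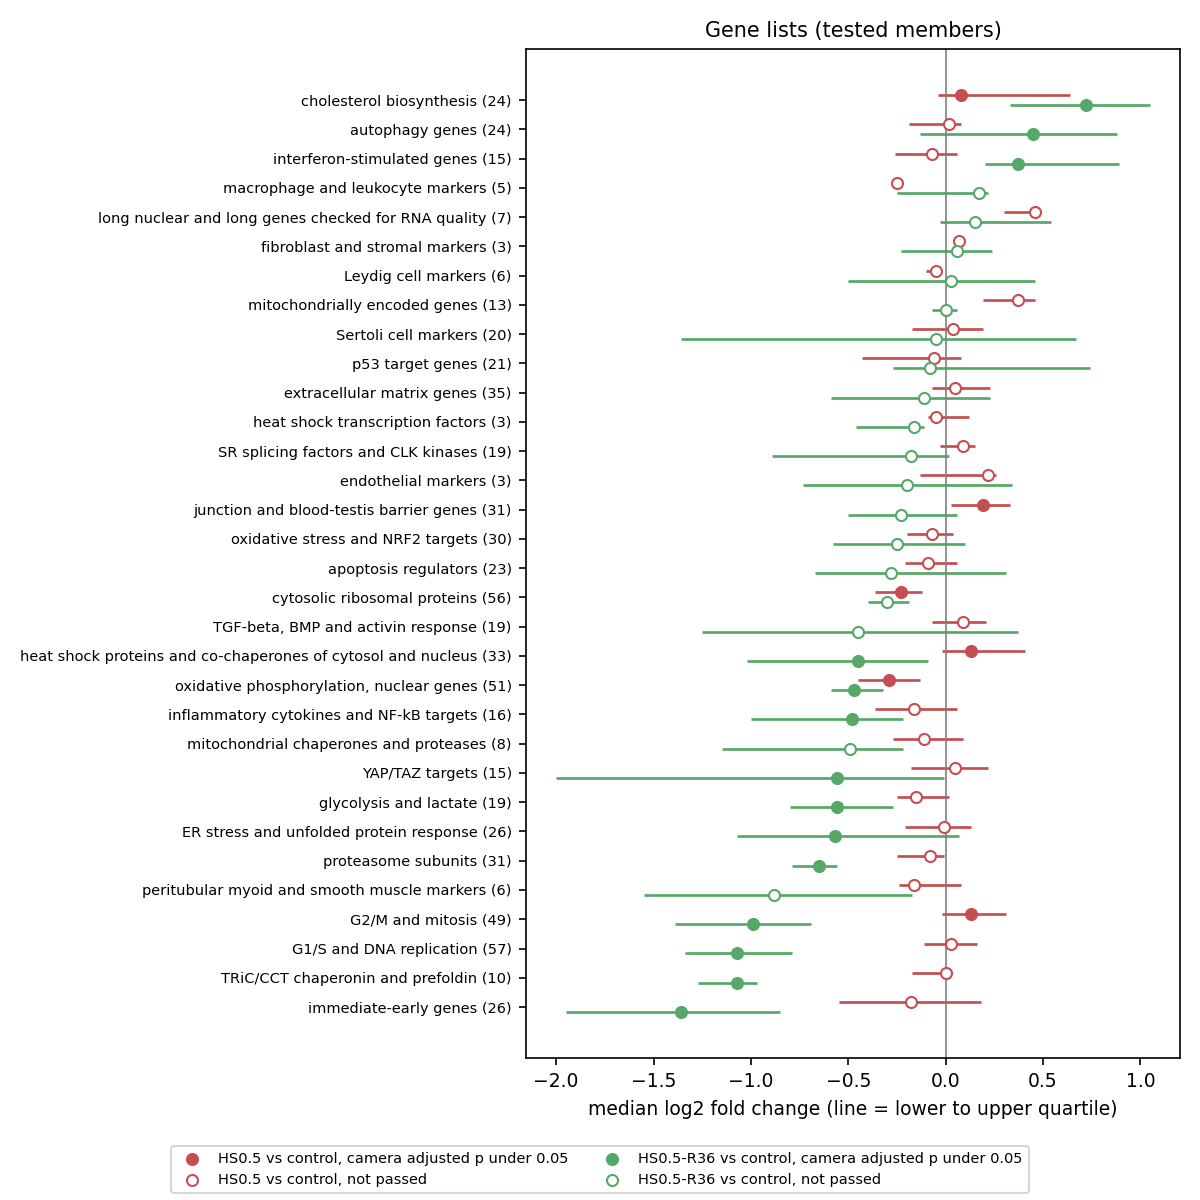
Median log2 fold change of the tested members of 32 gene lists at 0 h and at 36 h against control, with the range between the quartiles as a line and filled points where camera passed at the preset correlation. Proliferation and immediate-early lists lie near or below -1 at 36 h and cholesterol synthesis at 0.72, and under quantile normalization at 36 h the camera direction of the oxidative phosphorylation and ribosomal lists turns, though the median of the former stays negative.

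Among the members, TK1 fell from 70.5 to 17 FPKM, AURKB by 1.79, ANLN by 1.73, ORC1 by 1.68, UBE2C by 1.66, CDCA7 by 1.65, CCNB1 by 1.59 and MCM5 by 1.5. HSPB1 went from 379 to 96.4 FPKM (-1.90), the HSP90 co-chaperones FKBP4 and CDC37 fell by 1.91 and 1.29, HSP90AA1 by 1.54 and HSPH1 by 0.93. HSP70.2 stayed above control by 0.66 (limma adjusted p = 0.016, or 0.05 without control replicate 3 and 0.056 without HS0.5-R36 replicate 3), DNAJB1 was not called (-0.18, 0.33), and HSF1 fell by 0.77. HSPA8 fell by 0.44 (0.014), but the call was lost without HS0.5-R36 replicate 2 (0.055) and after rescaling (0.34), and the sign turned under quantile normalization (0.15). The chaperonin subunits CCT8 and TCP1 each fell by 1.33, the proteasome subunits PSMB3 and PSMD8 by 1.31 and 1.26, and the ER chaperone and amino acid response genes CHAC1, CRELD2, MANF and ASNS by 1.52, 1.45, 1.35 and 1.18. INSIG1 reached 26.4 FPKM (2.09), and HMGCS1 rose from 17.1 to 65.7 (1.89). Autophagy initiation and receptor genes rose too: GABARAPL1 from 6.63 to 23.1 FPKM (1.66), WIPI1 by 1.64, ULK1 by 1.60 and NBR1 by 1.52. MX2, IFIT1, IFIT2 and IFI44L rose by 1.45, 1.44, 1.2 and 1.00. The glycolytic genes PFKP and ENO1 fell by 1.46 and 1.03, the lactate transporter SLC16A1 by 1.17, and the respiratory chain genes ATP5MC1 and CYC1 by 1.10 and 1.03. LIF fell by 2.34, VCAM1 by 1.13, ANKRD1 by 2.30, AXL by 2.11, IER3 by 2.31 and GADD45B by 2.29.

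Among lists that did not pass at 36 h, the Sertoli markers went both ways, 6 up and 9 down of 20 (median -0.05, camera adjusted p = 0.58 by limma). SOX9, the factor that sets the Sertoli fate, fell from 6.47 to 1.24 FPKM (-1.74), WT1 by 0.92, the Sertoli hormone AMH from 22.3 to 8.09 FPKM (-1.35) and the gap junction gene GJA1 from 16.8 to 3.03 (-2.14), and these fell after rescaling as well. Junction genes were split, 7 up and 14 down of 31 (15 down adjusted over the list alone, 0.27), with TJP3 up by 1.74. The p53 targets were 9 up and 7 down of 21 (0.87), with PLK2 down by 2.62 and PMAIP1 by 2.06, and CDKN1A was not called (0.08, 0.46). It was called up after rescaling (0.43, 0.0016, and 0.46 without mitochondrial and the most abundant genes), quantile normalization (0.70) or removal of the length trend (0.23) and with library weights (0.21). Apoptosis regulators were 5 up and 12 down of 23 (0.58), with the pro-apoptotic BMF up from 0.799 to 9.92 FPKM (2.60). The TGF-beta list was 5 up and 11 down of 19 (6 and 11 adjusted over the list alone, 0.18), with the BMP antagonist GREM1 down by 2.83 and SKIL by 0.45, the matrix list 8 up and 13 down of 35 (0.58), and the NRF2 targets 5 up and 14 down of 30 (0.28). SR factors and CLK kinases were 3 up and 8 down of 19 (0.15), with SRSF3 down by 1.39. Mitochondrial chaperones were 1 up and 6 down of 8 (0.073), with HSPE1 and HSPD1 down by 1.64 and 1.2. Peritubular myoid markers were 4 down of 6 (0.073, and 0.023 after rescaling), ribosomal proteins 7 down of 56 (1 adjusted over the list alone, 0.073) and heat shock factors 1 down of 3 (0.56). Leydig markers were 2 up and 2 down of 6 (3 up alone, 0.85), with the steroidogenic CYP11A1 up from 12 to 253 reads over 3 libraries, a ratio of 16.6 (95% interval 9.32 to 32.5). Macrophage markers were 1 up of 5 (0.58), endothelial 1 up and 1 down of 3 (0.88), fibroblast 1 up and 1 down of 3 (0.86), mitochondrially encoded genes 1 down of 13 (none adjusted over the list alone, 0.95) and the long genes 1 up and 1 down of 7 (none up and 1 down adjusted over the list alone, 0.82). The germ cell list had 1 tested member and the histone list 2, too few for a test. Without a filter the mitochondrial chaperone (0.0057), SR (0.018), NRF2 (0.048), myoid (0.025) and ribosomal (0.0024) lists did pass. The ribosomal list also passed as down with the replicate block (0.045) and without control replicate 1 or 3 or HS0.5-R36 replicate 3 (0.0099, 0.0069 and 0.032), and as up after quantile normalization (0.044). Median and mean or test differed in sign for p53 targets, fibroblast markers and mitochondrially encoded genes. Medians of the ribosomal, junction, Sertoli, SR factor, matrix, heat shock factor, p53, apoptosis, NRF2 and endothelial lists turned positive after rescaling.

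Markers of other cell types were measured beside these groups. The kidney tubule genes SLC34A1, CDH16, ATP6V1B1 and PAX2, listed after the rise of CLDN8, LRP2 and DIO1 had been seen, had mean FPKM of 55.4, 58.4, 41.8 and 25.4 in control and 153, 113, 76.5 and 45.6 in HS0.5-R36. Of 18 such genes tested, 15 rose at 36 h and none fell (median 1.07, 1.51 after rescaling, limma), or 12 of 15 (median 0.95) without CLDN8, LRP2 and DIO1, but CDH6 fell without control replicate 2 and AQP1 fell after quantile normalization. At 0 h none of the 18 changed, and 2 fell without control replicate 2. Of 6 tested Sertoli lineage factors and hormones, 5 fell and 1 rose at 36 h (median -1.38, -1.33 after rescaling). DMRT1, INHA and LHX9 were listed at 0 in all control libraries. Of 18 epithelial markers, 6 rose and 8 fell at 36 h (7 and 5 after rescaling), and KRT7 went from 392 to 238 FPKM.

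**Figure D4:**
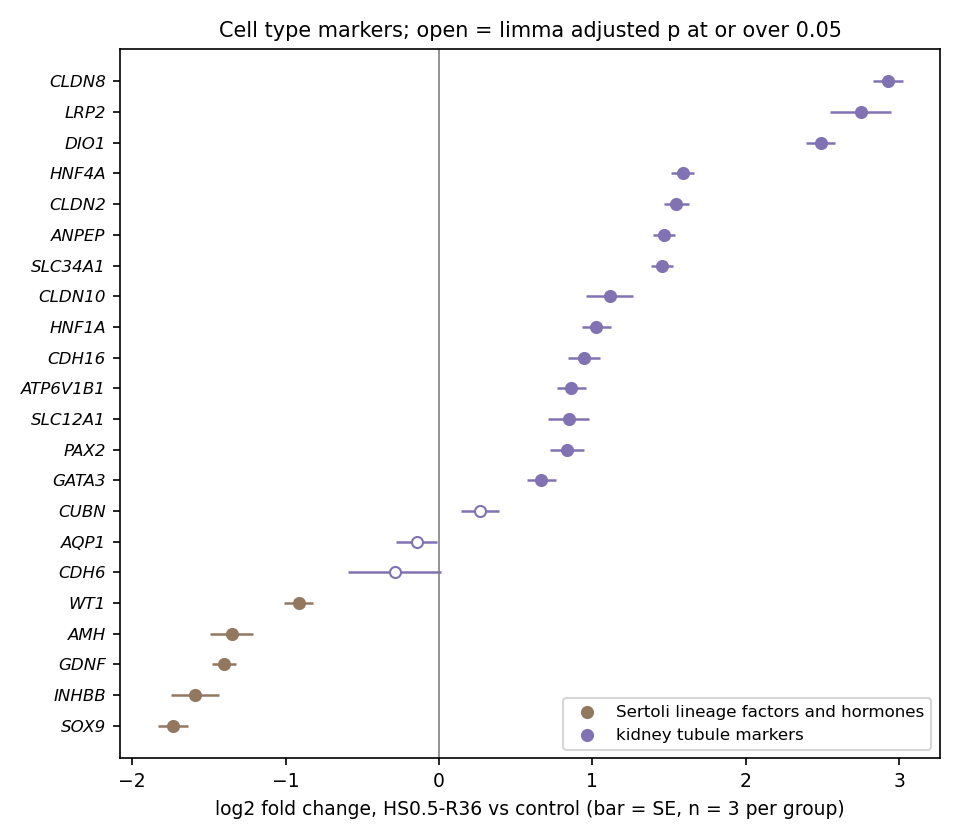
Log2 fold change at 36 h against control, with its SE (n = 3 per group), of tested kidney tubule markers and of Sertoli lineage factors and hormones, filled where limma's adjusted p was under 0.05. The figure leaves out 1 Sertoli gene, which rose, and 1 kidney tubule marker; the 5 Sertoli genes shown fell and most kidney tubule markers shown rose, and AQP1 falls past the threshold only under quantile normalization.

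Between 0 h and 36 h the induced chaperones came down. HSPA6 fell by 5.25 log2, HSP70.2 by 3.48, DNAJB1 by 2.84 and HSP90AA1 by 2.21, so that HSPA6 had 24 recovered reads at 36 h against 8232 at 0 h (ratio 0.00222, 95% interval 0.00142 to 0.00331). The integrin genes ITGA6 and ITGB1 fell by 1.96 and 1.75, the nectin gene NECTIN3 by 1.62 and the splicing factor gene SRSF7 by 1.22, and the membrane protein gene C1orf210 rose by 2.86. CDKN1A, an arrest gene that had fallen at 0 h, rose by 0.57 (limma adjusted p = 0.00055).

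From HS0.5 to HS0.5-R36, 7319 genes changed, 3301 up and 4018 down, 1887 of them at least 2-fold (885 up, 1002 down). Rises made up 45.1% of the calls, 68.7% of 7149 after rescaling, which moved the median of all genes by 0.32 from -0.07. Of the 32 lists, 13 passed camera (limma). The heat shock list had 28 of 33 down and 2 up (median -0.87, adjusted p = 1e-05, adjusted p = 0.47 with an estimated correlation). G1/S had 56 of 57 down (-1.16, 2.6e-14) and G2/M 47 of 49 down and 1 up (-1.15, 1.7e-12), each with adjusted p = 0.071 with an estimated correlation. Immediate-early genes (19 of 26 down and 3 up, 7.3e-05), the proteasome (24 of 31, 26 adjusted over the list alone, 0.00017), TRiC (10 of 10, 0.00099), SR factors and CLK kinases (12 of 19, 0.006), YAP/TAZ targets (9 of 15 down and 1 up, 0.012), junction genes (19 of 31 down and 5 up, 21 and 5 adjusted over the list alone, 0.038) and ER stress (17 of 26 down and 3 up, 17 and 6 adjusted over the list alone, 0.044) were down. Cholesterol synthesis (15 of 24 up and 1 down, 0.0019), autophagy (15 of 24 up and 5 down, 0.0042) and interferon genes (11 of 15 up and 2 down, 0.006) were up. For these 10 lists the estimated correlation gave, in the same order, an adjusted p of 0.17, 0.65, 0.52, 0.29, 0.35, 0.65, 0.43, 0.12, 0.12 and 0.12. With it 0 lists passed, 6 did so unadjusted, and 24 passed by fry. Other settings ended some of these passes. After quantile normalization the junction (0.49), ER stress (0.2), YAP/TAZ (0.13) and proteasome (0.056) lists no longer passed, nor with genes of at least 5 FPKM alone did the interferon (0.24), ER stress (0.11), junction (0.072) and YAP/TAZ (0.072) lists. The junction list did not pass after rescaling with or without mitochondrial and the most abundant genes (0.057 each), and ER stress did not with library weights (0.058) or protein-coding genes alone (0.054). Median and mean or test differed in sign for the Leydig, endothelial, fibroblast and ribosomal lists.

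Whether the early response persists was asked of the genes called at 0 h. Of the 263 that had risen, 115 were above control at 36 h too, 56 were below it and 92 were not called. Of the 152 that had fallen, 61 were below control at 36 h, 53 above it and 38 not called. So 176 genes were shared in direction, where independent lists of these sizes would share 75.1 rising and 52.6 falling. Simulated sets without group effects are no yardstick for this count: all 100 shared 0, but only 4 of them called any gene at 0 h. Over all genes the log2 changes correlated at 0.148, where these sets gave 0.461 on average (-0.654 to 0.972) from the shared controls alone. The covariance of the changes was 0.0348 against 0.0131, within the lowest and highest of the 100 sets (-0.0162 to 0.0941). Both comparisons use the same controls, which cannot be split, so part of the excess may come from them. INSIG1 is among genes up at both times, and CHAC1 is down at both. Moving back towards control between 0 h and 36 h were 261 genes, 168 of the risen and 93 of the fallen, where independent lists would give 92.1 and 43.7. Of the 100 simulated sets 1 gave 2519, since a shared group alone makes opposite signs, and 99 gave 0, most of them with no gene called at 0 h, so they are no yardstick here either. The log2 changes of the comparisons correlated at -0.294, where the simulated sets gave -0.415 on average (-0.973 to 0.807). The covariance of the changes was -0.0714 against -0.0138, within the lowest and highest of the sets (-0.0931 to 0.0266). Every set pooled the spread of all 9 libraries, control replicate 2 among them, which is wider than that of the shared HS0.5 libraries. These sets thus cannot exclude a return, and the excess over independent lists does not by itself show one. The shared count was 73 without control replicate 1, 89, 63 and 53 without HS0.5 replicates 1, 2 and 3, and 98 without HS0.5-R36 replicate 2 or 3. The count moving back was 104 without control replicate 1, 103, 65 and 59 without HS0.5 replicates 1, 2 and 3, and 121 and 129 without HS0.5-R36 replicates 2 and 3. Of the 7248 genes changed at 36 h, 285 (3.9%) had been called at 0 h, close to the 3.6% called at 0 h among all tested genes. The count of 285 cannot exceed the calls at 0 h, which were 105 and 88 without HS0.5 replicates 2 and 3.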

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

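Of the tests in this part, those of gene length, of a mislabelled HS0.5 or HS0.5-R36 library, of the scaling and of culture time were chosen after the result was seen, and the test of gene length as the whole cause was added after the test of its correlation had come out. Thinning and the splits of the samples were written beforehand, but the look at splits that leave the recovered libraries whole was added after.

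Several genes and lists were called in opposite directions at 0 h and at 36 h against control, with the difference between the times itself called by limma. HSPH1 had risen by 1.14 at 0 h and lay at -0.93 at 36 h, a difference of -2.06 log2. HSP90AA1 had risen by 0.67 and lay at -1.54, a difference of -2.21, and its call at 0 h was lost without control replicate 1 or any 1 of the HS0.5 libraries (limma adjusted p = 0.072, 0.053, 0.063 and 0.097). SKIL had risen by 0.86 and lay at -0.45, a difference of -1.30, and ADAMTS1 had fallen by 0.73 and lay at 0.45, a difference of 1.19. The call of SKIL at 0 h was lost without control replicate 1, any 1 of the HS0.5 libraries or HS0.5-R36 replicates 2 or 3 (limma adjusted p = 0.054 to 0.14), and that of ADAMTS1 without control replicate 1 or HS0.5 replicates 2 or 3 (0.055 to 0.084). The heat shock list differed by a median of -0.87 and the G2/M and mitosis list by -1.15. Neither list passed camera with an estimated correlation (adjusted p = 0.47 and 0.071 for the difference, and 0.83 for both at 0 h). The G2/M list had a median of only 0.13 at 0 h, with no member called. Over all genes 109 showed such a turn, 56 of the 263 up at 0 h and then down, and 53 of the 152 down and then up. Among all 11479 tested genes 3971 fell and 3277 rose at 36 h. A turn down was thus rarer among the risen than a fall among all genes, and a turn up somewhat more frequent among the fallen than a rise. The total of 109 by itself shows no excess of turns. Each turn needs a call at 0 h, and those calls fell from 415 to 88 without HS0.5 replicate 3. All comparisons share libraries, and no explanation of these turns was tested beyond those for the changes at 36 h.

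Control replicate 2 lay apart from control replicates 1 and 3, with an SD over genes of 0.428 log2 from their mean, where the HS0.5 and HS0.5-R36 libraries reached at most 0.252. An HS0.5 library under a control label is argued against by HSPA6, at 0.0153 FPKM in it and at least 24.0 in every HS0.5 library. A recovered library under that label is argued against by the score of control replicate 2 on the first principal component. That score was -27.4, where the recovered libraries lie at 50.3 to 51.8. Thinning control replicate 2 to the reads of control replicate 1 left the SD at 0.43 (a fall of -0.35%). Thinning keeps each gene's expected value and adds counting noise, so it could hardly lower the SD and cannot decide on deeper sequencing. Gene length may carry part of it: the deviation correlated with length at a Spearman rho of -0.458 over genes, which are not independent replicates, but control replicates 1 and 3 reached 0.395 and 0.416 because their own deviations contain replicate 2, so the comparison cannot tell its rho from theirs, and control 1 minus control 3 gave -0.136. Length is not the whole of it, since the SD was still 0.383 after the trend was removed, above the highest, 0.24, of the HS0.5 and HS0.5-R36 libraries. The long genes watched for RNA quality moved with this library, with a median of 0.46 at 0 h and 0.14 without control replicate 2. Being long, they cannot tell RNA quality from the length trend. Sequencing depth, RNA quality, handling and a biological difference of this culture stay open, the last 2 untested.

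The changes at 36 h against control are many, 7248 genes. The unstated scaling of the deposited values is argued against as their source, since 76.3% kept their call and direction after rescaling, and so is gene length, with 95.1% kept after the length trend was removed. The scaling may set the balance. Rises were 45.2% of the calls as deposited. They stayed at 45.2% of 7249 calls after median-of-ratios scaling, which divides each library by its median ratio to the gene means. The deposited values thus lay close to that scaling already. Rises were 50.5% of the calls after quantile normalization and 68.6% after rescaling, so neither direction can be called the larger. Recovery from heat, the biological explanation in the design, and 36 h more in culture, with any change in cell density, cannot be told apart, since there are 0 unheated libraries of that age. The falls of proliferation, immediate-early and YAP/TAZ genes could come from either. A change in the share of a second cell type by 36 h, taken up in the last part, is not excluded for them.

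With 10 splits of 6 libraries into 3 and 3, the splits are too few for a share under 0.05. The real splits called 415, 7248 and 7319 genes for HS0.5 with control, HS0.5-R36 with control and HS0.5-R36 with HS0.5, in each case in 1 of 10 splits, and the highest other count was 0 in each. For the lists, 8 splits at 0 h had at least the 6 of the real one, with 9 as the highest other. For HS0.5-R36 with control, 1 split had 14, with 13 as the highest other, and for HS0.5-R36 with HS0.5, 4 splits had at least 13, with 16 as the highest other. Of 100 splits of the 9 libraries, 2 shared at least 176 genes and 3 had at least 261 genes moving back, but this share does not decide on chance. Splits that parted the 3 recovered libraries gave at most 4 and 5 genes, and the highest other count, 5808 for both, came from splits that made these libraries the shared group, which points to the structure of the samples: they stand apart from the other 6. The 20 splits that leave the recovered libraries whole and outside the shared group are too few for a share under 0.05. With control and HS0.5 exchanged the counts of shared genes and of genes moving back change places, 261 and 176, and the highest of the 18 other splits was 0 for both.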

How the results depend on the processing

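The voom fit and the removal of the length trend were chosen after seeing the data, and every other alternative beforehand. Leaving out 1 library in turn, other pseudocounts, filters, scalings, variance models, a block and a fit of 2 groups were set against each named result. Stricter thresholds and other list tests are counted apart. Of 33 named genes called at 0 h, 17 kept their call and direction throughout, as did 92 of 102 in HS0.5-R36 with control and 90 of 97 in HS0.5-R36 with HS0.5. Of the lists, 3 of 6, 8 of 14 and 8 of 13 did. The cause was not tested for any change given here, unless said.

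The 415 genes changed at 0 h became 193 without a filter, where 20681 genes share the adjustment, 243 with FPKM of at least 5, where 8063 are tested, 191 after rescaling to the same sum and 241 when mitochondrial genes and the 20 most abundant were left out of it. They became 116 in a fit of only these groups, which has fewer samples, 88 at an adjusted p of 0.01 and 44 at a fold of at least 2. With limma's library weights they became 5163, with 51.2% of them rises; the weights ran from 0.0651 for control replicate 2 to 8.88 for HS0.5 replicate 2. Over the libraries left out they ran from 88 without HS0.5 replicate 3 to 457 without control replicate 2. In the same order of alternatives the 176 shared genes became 94, 109, 94 and, with the fit of the compared groups, 58, with 40 at 0.01 and 1576 with weights, and ran from 53 to 186 without 1 library. The 261 that moved back became 126, 155, 112, 137, 79, 58 at 0.01 and 3500 with weights, and ran from 59 to 315. Rescaling also makes the added 1 smaller beside the values.

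With replicate numbers as a block, 221 genes changed at 0 h, 108 were shared and 143 moved back, and 7039 and 7135 changed in the comparisons with HS0.5-R36, but the numbers are not known to be pairs. The counts of 7248 and 7319 moved past 1.5 times only with a fold of at least 2, to 1711 and 1887, and ran from 6467 to 7855 and from 6446 to 8465 without 1 library.

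The lists that passed, 6, 14 and 13, became 0, 0 and 0 with an estimated correlation and 3, 24 and 24 by fry, which asks another question. Without 1 library they ran from 3 (without control replicate 2) to 7 at 0 h, from 14 to 15 and from 13 to 15.

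Among results that passed in the main test or under the other setting, the direction of a test turned in the cases given here. Turns of tests that passed in neither are not listed, and medians of lists that did not pass turned more often. Under quantile normalization the oxidative phosphorylation list reached -0.022 with an upward test and the ribosomal list 0.208 at 36 h, HSPA8 0.148, and DYNC1H1 0.136 in HS0.5-R36 with HS0.5. The ribosomal list at 0 h had a median of 0 without control replicate 2 and of -0.354 without control replicate 3. By fry the p53 targets, with members both ways, tested opposite to camera at medians of -0.078 at 36 h and 0.358 in HS0.5-R36 with HS0.5, and the endothelial list at 0.28. Depth limits weakly expressed genes: SNORD54 had 39 reads and ssc-mir-221 68 over the 3 controls.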

Other observations

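The groups and genes of this part were chosen after their values were seen, and the tests on kidney markers after the rise of CLDN8, LRP2 and DIO1 had been seen. The test of the Sertoli share was written before its counts, but after the values of SOX9, WT1 and AMH were known. The tests of a change in share alone were added after the test of marker direction had come out.

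Small nucleolar RNAs, which guide the modification of ribosomal RNA and are released from introns of host genes, fell at 36 h in 99 of 180 tested genes, with 2 rises (limma, median -0.95). After rescaling 75 fell, and after the length trend was removed 40 fell and 7 rose, with a median of -0.36. At 0 h 13 fell and 4 rose, and the falls were 3 without control replicate 1 and 8 without HS0.5 replicate 2 or 3. After the length trend was removed 8 fell and 7 rose at 0 h, with a median of -0.02, so no direction of the class is given for 0 h. Their median length is 91 bases, and their reads cannot be told from reads of the host introns they lie in. The 6 tested genes of the ribosomal RNA class outside mitochondria fell at 36 h, and of 2 mitochondrial ribosomal RNA genes 1 rose.

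The collagen gene COL1A2 had a mean of 1533 FPKM in control and its partner in type I collagen, COL1A1, 2.26. At 36 h COL1A2 was at 2069 and COL1A1 at 1.29.

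The identity of the cells gave a hypothesis. In control 6 of 13 measured Sertoli lineage factors and hormones (46.2%) reached a mean of 1 FPKM, 1 short of the number that would have argued the other way. So did 16 of 22 kidney tubule markers (72.7%, or 13 of 19 without CLDN8, LRP2 and DIO1) and 16 of 20 epithelial markers (80%). Cells of another epithelial type may thus be present beside or in place of Sertoli cells. The most abundant kidney markers were CDH6 at 192 ± 82.5 (SD, n = 3), CDH16 at 58.4 and SLC34A1 at 55.4 FPKM, and no sort or gate is described. The most abundant of the 13 Sertoli genes were AMH at 22.3, WT1 at 7.965 and INHBB at 6.98 FPKM. These 13 are part of the preset Sertoli list, of which 19 of 32 measured members (59.4%) reached a mean of 1 FPKM, so by the wider list the count would have argued the other way. Of its members outside the 13, 13 of 19 (68.4%) did. None of the kidney markers is in another list, and epithelia of the Wolffian duct express several of them too, which was not tested. Of the epithelial markers 5 are in other lists. KRT8 and KRT18 among these, at 319 and 113 FPKM in control, belong to the preset Sertoli list. The epithelial share thus does not by itself speak against Sertoli cells. At 36 h, with CLDN8, LRP2 and DIO1 left out, 0 of 15 kidney markers fell and 12 rose, as a larger share of such cells would need, though CDH6 fell without control replicate 2 and AQP1 after quantile normalization. The epithelial markers went both ways at 36 h, 6 up and 8 down of 18, or 7 and 5 after rescaling. They do not show a larger share of epithelial cells in general. Whether a change in share alone is enough stays open. The 7 abundant risen markers spread over 2.09 log2, 22.9 times their mean SE and past the bound of 10 times set against it, but the widest rises among them are of genes that prompted the list, and the other 5 spread over 0.64 log2, which was 7.1 times their mean SE, between that bound and the 3 times set to go with it.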
